A study of Mus musculus with 24 samples.

How the data were processed

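RNA was measured in B16F10 mouse melanoma cells of 4 genotypes (a control knockout, an Rnf31 knockout, an Atg5 knockout and a double knockout) treated in 6-well plates with vehicle or TNFα (2 ng/ml, 24 h). Per the labels' protocols, total RNA came from 3 biological replicates per group and was extracted with a column kit for small samples, and a commercial provider prepared and sequenced the libraries. Whether the knockout lines were clones or pools, where the genes were edited, and the library kit and its strandedness are not given in the sources used here.

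As deposited, the values are expected counts, that is counts estimated per gene symbol and not normalized. The submitters' processing notes name STAR, RSEM and DESeq2 and the builds GRCm38 and mm10, with no versions or order of steps. The unit was inferred: the values are whole numbers with unequal totals, and 23 rows equal another row in every library, as when reads shared by copies of a gene are divided by estimation. The values were rounded to whole numbers before use, which changed none of them. Annotation, strand setting and filters are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and values of near-identical genes depend on how shared reads were divided. The table has 15739 rows, of which 1 has a blank name. That row held a mean of 0.140% of the counts and was left out of library sizes and tests. Totals over the 15738 named genes were 19425795 to 33385502 per library.

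Groups were taken from the sample labels. edgeR 4.0.16 in R 4.3.3 was run on the counts with TMM scaling, a low-count filter by the 8 groups (filterByExpr), and the quasi-likelihood test on a model of 8 group means over all 24 libraries. The filter removed 2211 genes and left 13527. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. The 13 comparisons were the TNFα response in each genotype, each knockout against control with vehicle, the difference of responses between genotypes, and the departure of the double knockout response difference from the sum of the single ones. Fold changes are edgeR's log2 estimates with standard errors, and levels are counts scaled by TMM library size (CPM) with the SD of 3 libraries. Of 25 gene lists, 24 had enough tested members for camera (limma 3.58.1, voom values, preset correlation 0.01), and 312 tests were adjusted together. Each was repeated with a correlation estimated per list. The added comparison of the double with the Atg5 knockout was not among the 312 and was adjusted over its own 24 lists. Counts of list members passing are given over all genes tested and adjusted over the list alone.

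Genes were named by a fixed rule. Its pools were Rnf31 and Atg5, the 12 largest changes in each direction of a comparison among called genes with at least 2 CPM in a group and no overlap between libraries (predicted genes and pseudogenes skipped), the 4 members of each list with the smallest adjusted p, 20 genes set by name (inflammatory, antigen-presentation, stress, pigment and cell cycle genes), and genes whose limits or departures have to be stated. Some genes of these pools are not reported here. Lists, comparisons, the naming rule and all alternatives but those marked below were chosen before the data were examined.

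Where a gene had few counts in a group, its fold was computed from summed counts with a 95% counting interval, or against a floor of 3 counts over the group where it had 0. Shares of counts have 95% Wilson intervals. Intervals and floors cover counting error only. Coordinates are from GENCODE M21 on GRCm38, which matched 15519 of the symbols. Transcript length is the longest annotated transcript, known for 13350 tested genes (98.7%). The length correction fitted each library's deviation on log2 length by lowess and entered it as an offset.

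The test was tested on data simulated from control vehicle levels with no length trend, with 100 genes changed 1.5-fold and 100 changed 2-fold. It recovered 86 and 95 for the TNFα response in control cells (13023 genes), 90 and 94 for that in the Atg5 knockout (13018 genes) and 67 and 93 for the response difference of the Atg5 knockout (13009 genes), with 8 false calls each. On simulated counts with a length trend in control vehicle libraries alone, 11 genes were called for that difference before the correction and 0 after it (13527 genes). Alternatives set beforehand were RLE size factors, no filter, a filter at a mean of 1 CPM, robust estimation of the spread, a test against a log2 fold change of 1 (glmTreat), DESeq2 1.42.0, a fit of only the groups compared, a replicate term and leaving out each library in turn. The length correction, the list tests without control vehicle replicate 2 and a comparison of the double with the Atg5 knockout were added after the data were seen. Every sample column was used. Overlaps between comparisons that share controls were set beside 20 simulations of unchanged groups.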

Results

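Transcripts were sequenced from B16F10 cells, a pigmented mouse melanoma line, in 4 genotypes under 2 treatments. The genotypes were a control knockout line, labelled wild type, an Rnf31 knockout, an Atg5 knockout and a double knockout of both genes. Rnf31 is the catalytic subunit of the linear ubiquitin chain assembly complex, which acts at the TNF receptor, and Atg5 is a conjugation factor needed to form autophagosomes. Each line received vehicle or TNFα, an inflammatory cytokine released by T cells among others, at 2 ng/ml for 24 h. The series concerns ways to make resistant tumour cells respond to cytokines from T cells, so the comparisons ask how the loss of each gene changed the untreated transcriptome and the response to TNFα. Each of the 8 groups held 3 libraries labelled as biological replicates, 24 in all. The counts assigned to named genes totalled 19425795 to 33385502 per library, and 13527 genes were tested. The leading 3 principal components held 48.1%, 13.8% and 6.41% of the variance, and the biological coefficient of variation was 6.17%. Libraries of the same group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 3.15 to 32.1. The values of 32.1 and 20.2 belonged to pairs with control vehicle replicate 2, and every other pair lay at or below 9.04. Sources used here do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries.

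The transcripts of the targeted genes were measured in every group. Atg5 (GRCm38 chromosome 10, 44268358 to 44364291, protein-coding) stood at 54.7 ± 6.26 CPM (counts scaled by library size; mean ± SD, n = 3) in control vehicle and 47.9 ± 1.68 in control TNFα libraries. In the Rnf31 knockout it stood at 44.9 ± 1.95 with vehicle and 42.6 ± 1.42 with TNFα. In the Atg5 knockout the values were 22.2 ± 2.35 and 23.1 ± 0.273, and in the double knockout 25.3 ± 1.44 and 24.9 ± 2.45. With vehicle, the log2 fold change ± SE against control was -1.30 ± 0.08, adjusted p = 3.43e-14 in the Atg5 knockout and -1.11 ± 0.08, adjusted p = 2.05e-12 in the double knockout (edgeR quasi-likelihood test, Benjamini-Hochberg). Atg5 was also lower in the Rnf31 knockout (-0.28 ± 0.07, adjusted p = 0.00261). Rnf31 (chromosome 14, 55591708 to 55603693, protein-coding) stood at 9.79 ± 1.08 CPM in control vehicle and 10.5 ± 0.340 in control TNFα libraries. The Rnf31 knockout had 8.04 ± 0.421 with vehicle and 7.61 ± 0.794 with TNFα, and the double knockout 6.62 ± 0.222 and 7.07 ± 0.340. In the Atg5 knockout Rnf31 was higher, at 13.2 ± 0.836 and 13.8 ± 1.11 CPM (0.43 ± 0.10, adjusted p = 3.22e-04 with vehicle). With vehicle, Rnf31 was lower in the double knockout (-0.57 ± 0.10, adjusted p = 3.26e-05) and in the Rnf31 knockout (-0.28 ± 0.10, adjusted p = 0.0211). The last of these calls was lost without control vehicle replicate 1 (-0.21, adjusted p = 0.118), control vehicle replicate 2 (adjusted p = 0.0682), Rnf31 knockout vehicle replicate 1 (adjusted p = 0.0568) or replicate 2 (adjusted p = 0.0505), and in a fit of the groups compared alone (-0.30, adjusted p = 0.0611). A small frameshift edit need not lower the transcript, and the edited positions are not given in the sources used here, so gene-level counts check these labels only in part.

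**Figure D1:**
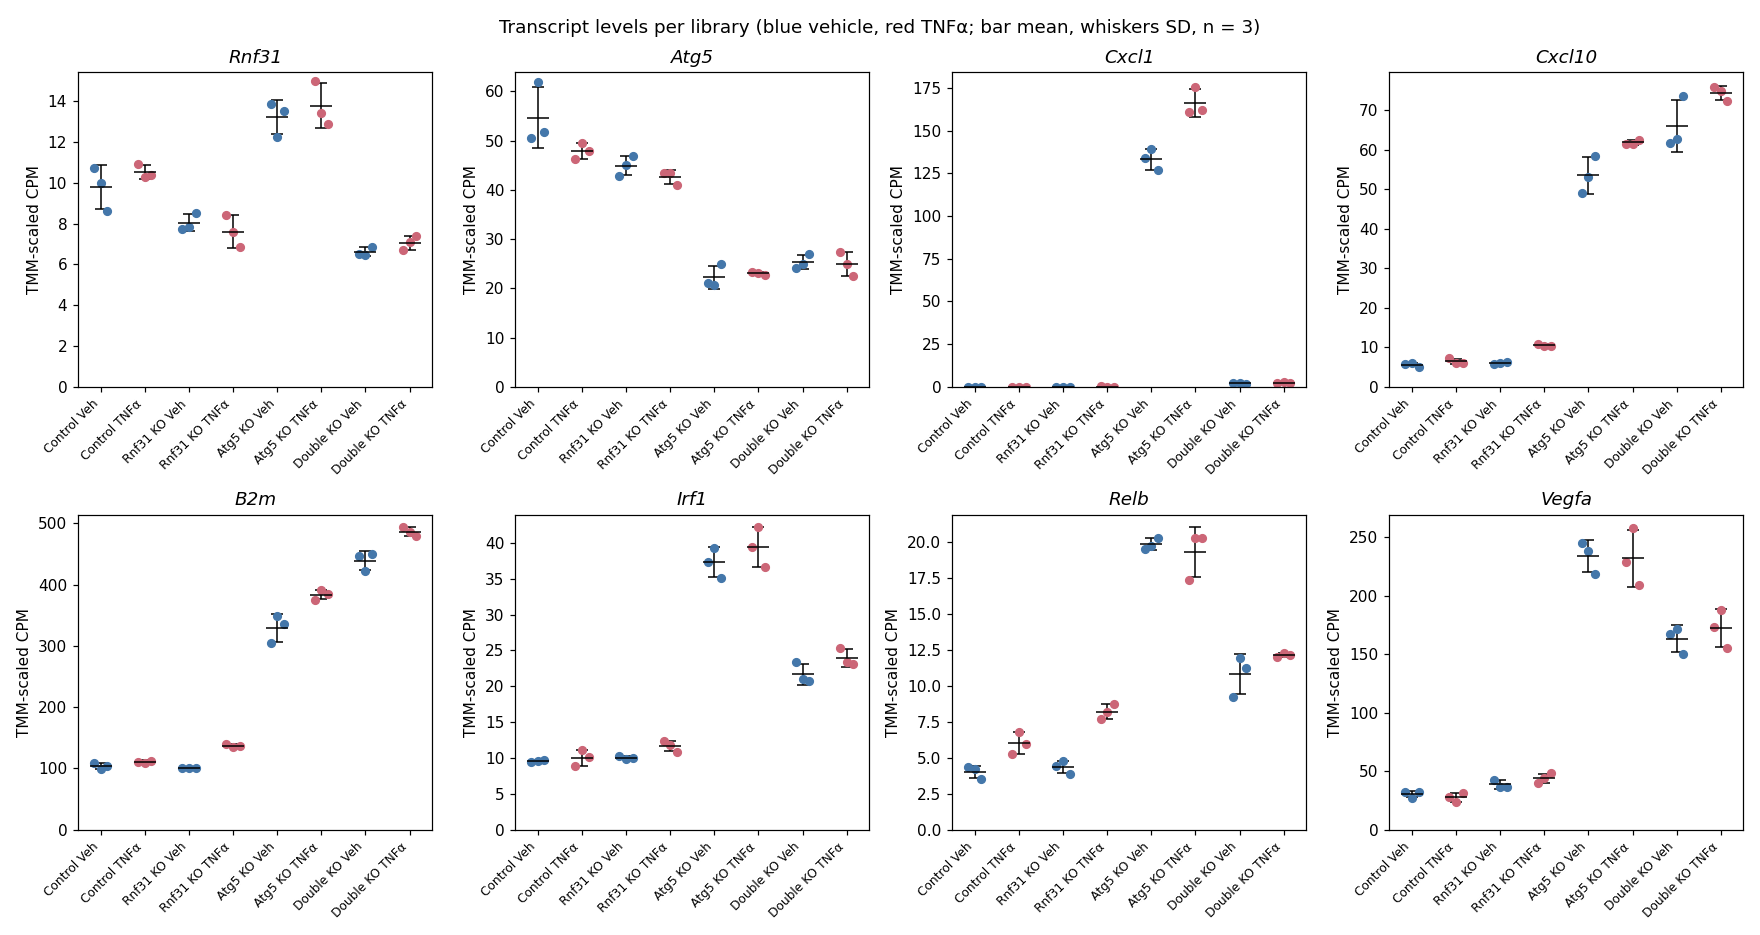
Transcript levels per library in TMM-scaled CPM (vertical axis) for 8 genes in the 8 groups (horizontal axis), with vehicle in blue, TNFα in red, the mean as a bar and the SD as whiskers (n = 3). Cxcl1 averaged 133 CPM in Atg5 knockout and 2.02 CPM in double knockout vehicle libraries, and B2m averaged 329.5 and 439 CPM there against 104 CPM in control.

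Atg5 knockout cells held far more Cxcl1 and Cxcl10 transcripts than control cells with no TNFα added. Cxcl1, a neutrophil chemokine (GRCm38 chromosome 5, 90891241 to 90893115), had 4 counts over the 3 control libraries and 11872 over the 3 knockout libraries, a 2916-fold higher level (95% counting interval 1139 to 10701, counting error only). Cxcl10, a T cell chemokine (chromosome 5, 92346638 to 92348889), was at 5.61 ± 0.425 CPM in control and 53.5 ± 4.58 CPM in the knockout (mean ± SD, n = 3). B2m, the shared light chain of MHC class I (chromosome 2, 122147686 to 122153083), was at 104 ± 5.20 and 329.5 ± 22.6 CPM. Vegfa, a hypoxia-induced growth factor (chromosome 17, 46016993 to 46032369), was at 30.5 ± 2.76 and 234 ± 13.7 CPM. In the edgeR test 8393 of 13527 genes changed, 4239 higher and 4154 lower, of which 1315 were higher and 329 lower by more than 2-fold.

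Among chemokines and cytokines, of 14 members tested, 11 were higher, 0 were lower and 3 were not called (11 higher and 0 lower adjusted over the list alone), and the median log2 fold change was 3.26 (camera adjusted p = 7.68e-05, 0.0305 with an estimated correlation). Log2 fold changes ± SE were 3.25 ± 0.08 for Cxcl10, 3.27 ± 0.13 for the chemokine Ccl5 and 2.45 ± 0.08 for the macrophage growth factor Csf1. For NF-kB targets and feedback genes, of 21 members tested, 19 were higher, 1 was lower and 1 was not called (20 higher and 1 lower adjusted over the list alone). The median was 1.52 (camera adjusted p = 1.14e-07, 0.0294 with an estimated correlation). They included the inhibitors Nfkbia (2.54 ± 0.12), Tnfaip3 (4.31 ± 0.22) and Nfkbiz (3.24 ± 0.10) and the TNFα-induced gene Tnfaip2 (1.72 ± 0.06). In the interferon-stimulated list, of 40 members tested, 38 were higher, 1 was lower and 1 was not called (39 higher and 1 lower adjusted over the list alone). Its median was 3.14, or 3.13 with members near 0 counts set at their bounds (camera adjusted p = 9.76e-18, 0.168 with an estimated correlation). The antiviral sensor Ddx58 (3.86 ± 0.11), the enzyme Oas1a (4.96 ± 0.12), the receptor chaperone Rtp4 (4.59 ± 0.13) and the transcription factors Irf9 (2.70 ± 0.08) and Irf1 (1.96 ± 0.08) were among them. Trim30a, an interferon-induced ubiquitin ligase, was 92.2-fold higher (95% counting interval 63.4 to 139.9). For MHC class I antigen presentation, of 20 members tested, 17 were higher, 2 were lower and 1 was not called (17 higher and 2 lower adjusted over the list alone). The median was 1.82 (camera adjusted p = 8.92e-07, 0.0607 with an estimated correlation). The heavy chain H2-K1 (chromosome 17, 33996017 to 34000347) rose by 3.97 ± 0.13, B2m by 1.67 ± 0.05, the peptide transporter subunit Tap1 by 2.92 ± 0.19 and the loading factor Tapbp by 2.82 ± 0.06 on the log2 scale. For immune ligands and checkpoints, of 11 members tested, 9 were higher, 0 were lower and 2 were not called (9 higher and 0 lower adjusted over the list alone). The median was 1.13 (camera adjusted p = 0.00189, 0.174 with an estimated correlation). Cd274, which encodes PD-L1, changed by 0.80 ± 0.16, and Tnfrsf9, the receptor 4-1BB, was 257-fold higher (95% counting interval 176 to 389.6). Every gene named here had an adjusted p of at most 6.34e-05 (Cd274). H2-K1, Oas1a and Trim30a belong to families of similar genes, so their values depend on how shared reads were assigned, and 23 rows of the table were identical to another row in every library.

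For glycolysis and hypoxia genes, of 25 members tested, 24 were higher, 1 was lower and 0 were not called (24 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 1.75 (camera adjusted p = 9.76e-18, 0.212 with an estimated correlation), among them the collagen hydroxylase subunit P4ha1 (2.00 ± 0.06), Vegfa (2.94 ± 0.10), the hypoxia-induced Ndrg1 (2.34 ± 0.08) and the glucose transporter Slc2a1 (2.10 ± 0.08). For the integrated stress response, of 26 members tested, 19 were higher, 4 were lower and 3 were not called (19 higher and 4 lower adjusted over the list alone). The median was 0.70 (camera adjusted p = 3.21e-06, 0.174 with an estimated correlation). The folate enzyme Aldh1l2 (3.71 ± 0.07), the transcription factor Atf3 (2.99 ± 0.10), the glutathione-degrading enzyme Chac1 (2.53 ± 0.10) and the mTORC1 inhibitor Ddit4 (3.44 ± 0.14) rose. Among dedifferentiation, mesenchymal and matrix genes, of 22 members tested, 17 were higher, 1 was lower and 4 were not called (17 higher and 3 lower adjusted over the list alone). The median was 0.90 (camera adjusted p = 1.16e-05, 0.174 with an estimated correlation). They included fibronectin, Fn1 (3.64 ± 0.08), the receptor kinase Axl (2.61 ± 0.07) and Ccn1 (1.85 ± 0.09). Immediate early genes, which also respond to handling, moved the same way: of 15 members tested, 10 were higher, 2 were lower and 3 were not called (11 higher and 2 lower adjusted over the list alone). The median was 1.20 (camera adjusted p = 0.00299, 0.174 with an estimated correlation). In the TNF receptor complex list, of 21 members tested, 13 were higher, 1 was lower and 7 were not called (13 higher and 1 lower adjusted over the list alone). The median was 0.24 (camera adjusted p = 0.0143, 0.174 with an estimated correlation), and members included the deubiquitinase Cyld (0.87 ± 0.06) and the ubiquitin ligase Birc2 (1.07 ± 0.10). For autophagy genes, of 36 members tested, 20 were higher, 5 were lower and 11 were not called (20 higher and 5 lower adjusted over the list alone). The median was 0.25 (camera adjusted p = 0.0111, 0.104 with an estimated correlation). Adjusted p-values of the genes named here were at most 4.68e-10.

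For melanocyte pigmentation in the Atg5 knockout, of 19 members tested, 1 was higher, 16 were lower and 2 were not called (1 higher and 16 lower adjusted over the list alone), with a median log2 fold change of -0.55 (camera adjusted p = 6.59e-06, 0.168 with an estimated correlation). Lower members were the melanosome transporters Slc45a2 (-1.02 ± 0.04) and Slc24a5 (-0.85 ± 0.04), the channel Trpm1 (-1.16 ± 0.06) and the melanosome protein Mlana (-0.95 ± 0.05). For proliferation genes, of 32 members tested, 2 were higher, 26 were lower and 4 were not called (2 higher and 26 lower adjusted over the list alone). The median was -0.35 (camera adjusted p = 3.72e-06, 0.118 with an estimated correlation), and members included the ribonucleotide reductase subunit Rrm2 (-0.81 ± 0.04), the mitotic regulators Cdc20 (-0.88 ± 0.05) and Ccnb1 (-0.69 ± 0.04) and the replication clamp Pcna (-0.69 ± 0.04). Of the chaperones of the endoplasmic reticulum, of 16 members tested, 3 were higher, 11 were lower and 2 were not called (3 higher and 11 lower adjusted over the list alone). The median was -0.37 (camera adjusted p = 0.00471, 0.272 with an estimated correlation). Among them were Manf (-0.97 ± 0.06) and Hspa5 (-0.62 ± 0.05), the latter encoding the chaperone BiP. The strongest falls outside the lists included the transcription factor Klf15 (-2.68 ± 0.09), the imprinted gene Mest (-2.73 ± 0.14) and the butyrophilin Btn2a2 (-3.98 ± 0.14). Each adjusted p was at most 5.68e-12. Transcripts encoded by the mitochondrial genome, recorded as a sign of RNA quality, moved with these groups: of 13 members tested, 0 were higher, 9 were lower and 4 were not called (0 higher and 9 lower adjusted over the list alone). The median was -0.72 (camera adjusted p = 0.0128, 0.568 with an estimated correlation). Their camera call was lost after a correction for transcript length (adjusted p = 0.0888).

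**Figure D2:**
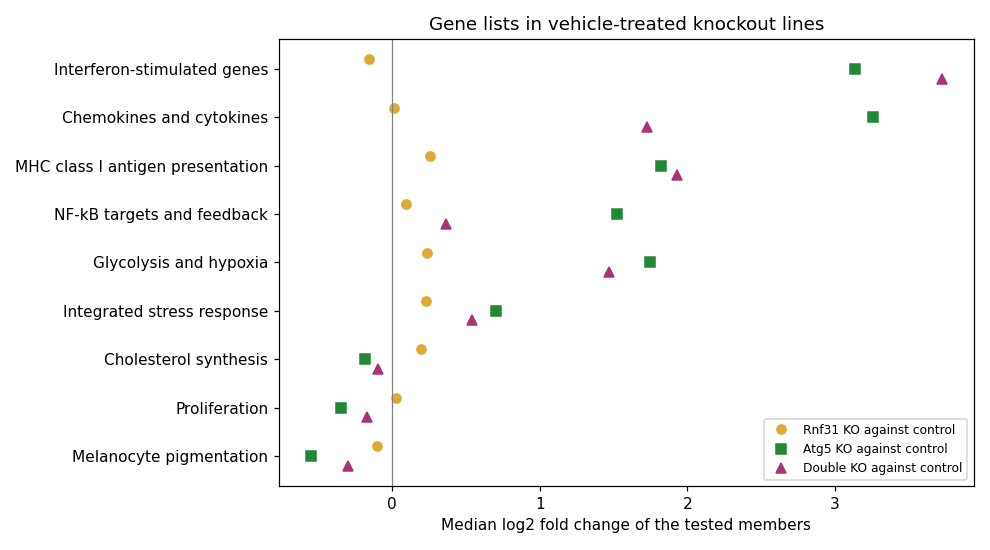
Median log2 fold change of the tested members (horizontal axis) of 9 gene lists (vertical axis) in Rnf31 knockout (circles), Atg5 knockout (squares) and double knockout (triangles) against control cells, vehicle libraries, n = 3 per group. The interferon-stimulated median was -0.15 in the Rnf31 knockout, 3.14 in the Atg5 knockout and 3.72 in the double knockout, and the NF-kB median was 0.10, 1.52 and 0.37.

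Double knockout cells also held more B2m and Cxcl10 transcripts than control cells before treatment. B2m was at 104 ± 5.20 CPM in control and 439 ± 14.9 CPM in the double knockout (mean ± SD, n = 3), and Cxcl10 at 5.61 ± 0.425 and 66.0 ± 6.58 CPM. Cxcl1 had 169 counts over the 3 double knockout libraries, 44.0-fold above control (95% counting interval 17.2 to 161). In the edgeR test 7093 genes changed, 3417 higher and 3676 lower, of which 657 were higher and 302 lower by more than 2-fold.

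Of the interferon-stimulated list, of 40 members tested, 40 were higher, 0 were lower and 0 were not called (40 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 3.72 (camera adjusted p = 1.41e-32, 0.0435 with an estimated correlation). Members with large changes were Oas1a (5.59 ± 0.12), Rtp4 (5.73 ± 0.12) and Ddx58 (4.48 ± 0.11), the antiviral tether Bst2 (3.10 ± 0.07) and the transcription factor Irf1 (1.18 ± 0.08). For MHC class I, of 20 members tested, 17 were higher, 1 was lower and 2 were not called (17 higher and 1 lower adjusted over the list alone). The median was 1.93 (camera adjusted p = 1.33e-08, 0.0305 with an estimated correlation), and members included H2-K1 (3.74 ± 0.13), B2m (2.08 ± 0.05), Tap1 (2.67 ± 0.19) and Tapbp (2.30 ± 0.06). Of the chemokines and cytokines, of 14 members tested, 9 were higher, 0 were lower and 5 were not called (9 higher and 0 lower adjusted over the list alone). The median was 1.72 (camera adjusted p = 0.00324, 0.0903 with an estimated correlation), and members included Cxcl10 (3.55 ± 0.08) and Ccl5 (3.47 ± 0.13). In the NF-kB list, of 21 members tested, 12 were higher, 1 was lower and 8 were not called (12 higher and 1 lower adjusted over the list alone). The median was 0.37 (camera adjusted p = 0.00395, 0.174 with an estimated correlation). Its members Nfkbia (1.04 ± 0.12) and Tnfaip3 (3.21 ± 0.23) and the subunit Relb (1.43 ± 0.12) rose, and Tnfrsf9 was 27.0-fold higher (95% counting interval 18.5 to 40.9). For glycolysis and hypoxia, of 25 members tested, 23 were higher, 1 was lower and 1 was not called (23 higher and 1 lower adjusted over the list alone). The median was 1.47 (camera adjusted p = 1.50e-18, 0.195 with an estimated correlation), and members included P4ha1 (1.47 ± 0.06) and Vegfa (2.42 ± 0.10), the hexokinase Hk1 (1.86 ± 0.08) and Slc2a1 (1.70 ± 0.08). In the integrated stress response list, of 26 members tested, 17 were higher, 4 were lower and 5 were not called (17 higher and 4 lower adjusted over the list alone). The median was 0.54 (camera adjusted p = 6.01e-06, 0.174 with an estimated correlation), and members included Aldh1l2 (2.48 ± 0.06), Atf3 (2.13 ± 0.10) and Chac1 (1.91 ± 0.10). Among dedifferentiation and matrix genes, of 22 members tested, 12 were higher, 3 were lower and 7 were not called (12 higher and 3 lower adjusted over the list alone). The median was 0.28 (camera adjusted p = 0.0124, 0.38 with an estimated correlation), and members included Fn1 (1.95 ± 0.08) and Axl (1.06 ± 0.08).

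Pigmentation genes were lower in the double knockout: of 19 members tested, 4 were higher, 13 were lower and 2 were not called (4 higher and 13 lower adjusted over the list alone), with a median log2 fold change of -0.30 (camera adjusted p = 0.00599, 0.309 with an estimated correlation). Trpm1 changed by -2.35 ± 0.07 and Mlana by -0.60 ± 0.05. For proliferation, of 32 members tested, 4 were higher, 20 were lower and 8 were not called (4 higher and 20 lower adjusted over the list alone). The median was -0.17 (camera adjusted p = 0.0264, 0.377 with an estimated correlation), and this call was lost after the length correction (adjusted p = 0.0869). For NRF2 targets, of 21 members tested, 6 were higher, 9 were lower and 6 were not called (6 higher and 9 lower adjusted over the list alone). The median was -0.10 (camera adjusted p = 0.284, 0.566 with an estimated correlation), and the detoxifying enzymes Gsta4 (-3.70 ± 0.17) and Nqo1 (-1.55 ± 0.14) fell, as did the myelin protein gene Mbp (-3.84 ± 0.11). Setbp1 had 1 count over the control libraries and 973 over the double knockout libraries, a 1013-fold higher level (95% counting interval 182 to 40021). Btn2a2 had 1158 counts in control and 1 in the double knockout, a 1112-fold lower level (95% counting interval 199.6 to 43922). The small heat shock protein gene Hspb1 had 155 counts in control and 0 in the double knockout, at least 49.6-fold lower against a floor of 3 counts over the group. Genes named for this comparison other than Atg5 and Rnf31 had an adjusted p of at most 4.38e-08 (Nfkbia). Mitochondrial transcripts were lower beside these groups: of 13 members tested, 0 were higher, 7 were lower and 6 were not called (0 higher and 7 lower adjusted over the list alone). The median was -0.42 (camera adjusted p = 0.0457, 0.63 with an estimated correlation). That call was lost without control vehicle replicate 2 (adjusted p = 0.145) and after the length correction (adjusted p = 0.345).

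Rnf31 knockout cells differed from control cells in many genes by small amounts. Map3k14, the kinase NIK of the non-canonical NF-kB pathway, was at 4.73 ± 0.688 CPM in control and 18.1 ± 1.72 CPM in the knockout (mean ± SD, n = 3; log2 fold change ± SE 1.93 ± 0.12). Chac1 was at 6.14 ± 0.625 and 16.3 ± 0.688 CPM, and the natriuretic peptide gene Nppb at 62.6 ± 12.3 and 20.9 ± 1.15 CPM (-1.59 ± 0.11). Setbp1 had 1 count over the control libraries and 236 over the knockout libraries, a 247-fold higher level (95% counting interval 44.4 to 9766). Smad6, an inhibitor of BMP signalling, changed by 1.75 ± 0.19 and the receptor Fgfr3 by 1.52 ± 0.11. By edgeR 6165 genes changed, 3261 higher and 2904 lower, of which 84 were higher and 105 lower by more than 2-fold. Tested against a 2-fold change, 6 genes passed.

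In the cholesterol synthesis list, of 22 members tested, 12 were higher, 0 were lower and 10 were not called (13 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.20 (camera adjusted p = 6.21e-04, 0.272 with an estimated correlation). Higher members were the regulator Srebf2 (0.44 ± 0.05) and the enzyme Fdps (0.33 ± 0.05). For the integrated stress response, of 26 members tested, 14 were higher, 2 were lower and 10 were not called (14 higher and 2 lower adjusted over the list alone). The median was 0.23 (camera adjusted p = 6.81e-04, 0.272 with an estimated correlation), and members included Chac1 (1.41 ± 0.10), asparagine synthetase Asns (0.64 ± 0.05) and the folate enzymes Mthfd2 (0.52 ± 0.04) and Shmt2 (0.48 ± 0.05). Of the endoplasmic reticulum chaperones, of 16 members tested, 9 were higher, 0 were lower and 7 were not called (9 higher and 0 lower adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.0101, 0.288 with an estimated correlation), and members included Herpud1 (0.55 ± 0.05), Sel1l (0.35 ± 0.05) and Hyou1 (0.30 ± 0.05). For glycolysis and hypoxia, of 25 members tested, 12 were higher, 1 was lower and 12 were not called (13 higher and 1 lower adjusted over the list alone). The median was 0.24 (camera adjusted p = 0.0052, 0.656 with an estimated correlation), and members included Ndrg1 (0.61 ± 0.08), the hexokinase Hk2 (0.66 ± 0.11) and the oxygen sensor Egln3 (0.85 ± 0.15). The p53 targets were lower: of 19 members tested, 1 was higher, 10 were lower and 8 were not called (1 higher and 10 lower adjusted over the list alone). The median was -0.22 (camera adjusted p = 0.0215, 0.285 with an estimated correlation), and members included Phlda3 (-0.40 ± 0.05), Ccng1 (-0.63 ± 0.08) and Mdm2 (-0.34 ± 0.05). For lysosomal genes, of 30 members tested, 3 were higher, 15 were lower and 12 were not called (3 higher and 15 lower adjusted over the list alone). The median was -0.10 (camera adjusted p = 0.0128, 0.269 with an estimated correlation). Of the pigmentation genes, of 19 members tested, 4 were higher, 11 were lower and 4 were not called (5 higher and 11 lower adjusted over the list alone). The median was -0.10 (camera adjusted p = 0.0326, 0.437 with an estimated correlation), a call lost after the length correction (adjusted p = 0.0884). They included tyrosinase, Tyr (-0.61 ± 0.06), and the melanocortin receptor Mc1r (-0.39 ± 0.04). For NRF2 targets, of 21 members tested, 5 were higher, 9 were lower and 7 were not called (5 higher and 9 lower adjusted over the list alone). The median was -0.02 (camera adjusted p = 0.168, 0.485 with an estimated correlation), and without control vehicle replicate 2 the list passed (adjusted p = 0.0371). The enzymes Blvrb (-1.14 ± 0.09), Nqo1 (-0.999 ± 0.13) and Gsta4 (-0.98 ± 0.13) and the ferritin chain Fth1 (-0.61 ± 0.04) fell.

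Nuclear genes of oxidative phosphorylation were lower in the Rnf31 knockout: of 28 members tested, 1 was higher, 21 were lower and 6 were not called (1 higher and 21 lower adjusted over the list alone), with a median log2 fold change of -0.35 (camera adjusted p = 2.39e-07, 0.366 with an estimated correlation). After the length correction the median was -0.08. Cox4i1, a subunit of complex IV, changed by -0.55 ± 0.07. Mitochondrially encoded transcripts moved with them: of 13 members tested, 0 were higher, 10 were lower and 3 were not called (0 higher and 10 lower adjusted over the list alone). The median was -0.40 (camera adjusted p = 0.00475, 0.533 with an estimated correlation), a call lost after the length correction (adjusted p = 0.417). For NF-kB targets, of 21 members tested, 6 were higher, 3 were lower and 12 were not called (6 higher and 3 lower adjusted over the list alone), with a median of 0.10, and the list did not pass (camera adjusted p = 0.566), while the subunit Nfkb2 rose (0.57 ± 0.09). The interferon-stimulated list did not pass either (camera adjusted p = 0.454): of 40 members tested, 2 were higher, 7 were lower and 31 were not called (2 higher and 5 lower adjusted over the list alone), with a median of -0.15. Its members Isg15 (-1.04 ± 0.16), Ifit1 (-1.004 ± 0.13) and Ifit3 (-0.81 ± 0.17) and Gbp2 (-0.76 ± 0.18) fell. Genes named for this comparison outside the targeted pair had an adjusted p of at most 0.00111 (Gbp2). The length correction left 5287 genes called, 4306 of them among the 6165.

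The 3 knockout comparisons shared the same 3 control vehicle libraries, so part of any excess overlap between them may come from those libraries. The Atg5 and double knockouts shared 2759 higher and 2862 lower genes, against 1071 and 1129 for independent lists of these sizes. Across genes, which are not independent replicates, their fold changes had a Pearson r of 0.703 and a covariance of 0.522. Simulated unchanged groups set against the same controls gave an r of 0.503 and a covariance of 0.0264 over 20 simulations. The Rnf31 and Atg5 knockouts shared 1523 higher and 1611 lower genes (1022 and 892 for independent lists), with an r of 0.204 (0.507 simulated) and a covariance of 0.0864 (0.0266 simulated). For the Rnf31 and double knockouts the shared genes numbered 1660 and 1772 (824 and 789 for independent lists), with an r of 0.303 (0.498 simulated) and a covariance of 0.117 (0.0262 simulated). The 3 controls are too few to split with 2 in each part.

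By edgeR, TNFα changed 13 genes in control, 158 in Rnf31 knockout, 0 in Atg5 knockout and 18 in double knockout cells, and DESeq2 called 682, 244, 69 and 72. In the Rnf31 knockout, Relb, a non-canonical NF-kB subunit (GRCm38 chromosome 7, 19606217 to 19629438), rose from 4.34 ± 0.430 to 8.18 ± 0.526 CPM (mean ± SD, n = 3), Cxcl10 from 6.07 ± 0.199 to 10.5 ± 0.238 CPM and B2m from 101 ± 0.507 to 137 ± 2.62 CPM. Rgs16, a brake on G protein signalling, rose from 13.9 ± 0.505 to 26.1 ± 0.536 CPM. Etv5, a transcription factor downstream of ERK signalling, fell from 14.4 ± 0.758 to 8.91 ± 0.538 CPM. Of the 158 genes in this line 122 were higher and 36 lower, with 1613 at an unadjusted p under 0.05 where chance gives 676. The 244 genes of DESeq2 were 159 higher and 85 lower.

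For NF-kB targets in the Rnf31 knockout, of 21 members tested, 4 were higher, 0 were lower and 17 were not called (7 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.12 (camera adjusted p = 1.88e-04, 0.0879 with an estimated correlation). Among them were Relb (0.92 ± 0.12), Nfkb2 (0.40 ± 0.08) and Nfkbia (0.53 ± 0.12). The Nfkb2 call was lost without vehicle replicate 1 (adjusted p = 0.0588) or TNFα replicate 3 (adjusted p = 0.0513), and the Nfkbia call without vehicle replicate 2 (adjusted p = 0.185), vehicle replicate 3 (adjusted p = 0.0552), TNFα replicate 1 (adjusted p = 0.0705) or TNFα replicate 3 (adjusted p = 0.112). For MHC class I, of 20 members tested, 3 were higher, 0 were lower and 17 were not called (4 higher and 0 lower adjusted over the list alone), with a median of -0.01, a mean of 0.06 and an upward test (camera adjusted p = 0.0457, 0.366 with an estimated correlation). That call was lost without control vehicle replicate 2 (adjusted p = 0.0519). Members B2m (0.45 ± 0.05) and Tapbp (0.54 ± 0.06) rose, as did the chemokine Cxcl10 (0.78 ± 0.09). Of the immediate early genes, of 15 members tested, 3 were higher, 0 were lower and 12 were not called (4 higher and 1 lower adjusted over the list alone). The median was 0.16 (camera adjusted p = 0.0153, 0.269 with an estimated correlation), and members included Jun (0.33 ± 0.06). The stress-induced factor Atf3 (0.74 ± 0.10), the MAP kinase phosphatase Dusp10 (0.74 ± 0.11), Rgs16 (0.91 ± 0.08), the adhesion molecule L1cam (0.64 ± 0.10) and Serpinb9b (0.83 ± 0.16) also rose. Among dedifferentiation and matrix genes, of 22 members tested, 1 was higher, 0 were lower and 21 were not called (6 higher and 0 lower adjusted over the list alone). The median was 0.13 (camera adjusted p = 7.26e-05, 0.212 with an estimated correlation). In the pigmentation list, of 19 members tested, 0 were higher, 4 were lower and 15 were not called (0 higher and 5 lower adjusted over the list alone). The median was -0.06 (camera adjusted p = 3.63e-04, 0.233 with an estimated correlation). Its lower members included the melanosome proteins Oca2 (-0.44 ± 0.07) and Slc45a2 (-0.20 ± 0.04) and Trpm1 (-0.44 ± 0.06). Other genes that fell were Etv5 (-0.70 ± 0.12), the ERK phosphatase Dusp6 (-0.38 ± 0.06), Mest (-0.61 ± 0.12) and Tinagl1 (-0.47 ± 0.08). Called genes named here had an adjusted p of at most 0.0201 (Nfkbia). For mitochondrial transcripts, of 13 members tested, 0 were higher, 0 were lower and 13 were not called (6 higher and 0 lower adjusted over the list alone). The median was 0.28 (camera adjusted p = 6.08e-06, 0.309 with an estimated correlation). The count fell to 87 without vehicle replicate 1, 87 without vehicle replicate 2 and 72 without TNFα replicate 3, and was 331 in a fit of these 6 libraries alone.

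In control cells, TNFα raised 13 genes and lowered none by edgeR, with 2945 genes at an unadjusted p under 0.05 and 682 called by DESeq2 (383 higher and 299 lower). Among the 13 were the ubiquitin ligase Ubr4 (0.41 ± 0.07), the protease Furin (0.38 ± 0.06) and the histone methyltransferase Kmt2d (0.34 ± 0.05), given as log2 fold change ± SE with adjusted p-values of at most 0.0123. Ubr4 was at 60.1 ± 4.87 CPM with vehicle and 80.0 ± 1.60 CPM with TNFα (mean ± SD, n = 3). Known TNFα and interferon targets did not pass: Nfkbia stood at 0.19 ± 0.13, adjusted p = 0.389, Cxcl10 at 0.20 ± 0.10, adjusted p = 0.247 and B2m at 0.09 ± 0.05, adjusted p = 0.26. Relb did not pass either (0.58 ± 0.12, adjusted p = 0.0551), but did without a filter (adjusted p = 0.0447), with the stricter filter (0.0364), with robust spread (0.0374) and without vehicle replicate 1 (0.00928). For NF-kB targets, 0 of 21 members tested were called (2 higher and 0 lower adjusted over the list alone). The longest annotated transcripts of the 13 genes had a median of 13215 nt, against 3223 nt over all tested genes, and 0 genes were called after the length correction, as the folds shrank (Ubr4 0.23 ± 0.06, Furin 0.31 ± 0.06, Kmt2d 0.14 ± 0.06). In the oxidative phosphorylation list, 0 of 28 members tested were called (1 higher and 17 lower adjusted over the list alone). The median was -0.16 (camera adjusted p = 2.13e-08, 0.328 with an estimated correlation), or -0.03 after the length correction. The count of 13 became 2200 without vehicle replicate 1, 2 without vehicle replicate 2, 0 without vehicle replicate 3, 2 without TNFα replicate 1, 5 without TNFα replicate 2 and 0 without TNFα replicate 3. The Ubr4 call was lost without vehicle replicate 3 (adjusted p = 0.0728), TNFα replicate 1 (adjusted p = 0.0555) or TNFα replicate 3 (adjusted p = 0.0831). The Furin call was lost without vehicle replicate 2 (adjusted p = 0.185), vehicle replicate 3 (adjusted p = 0.0728) or TNFα replicate 3 (adjusted p = 0.0831), and the Kmt2d call was lost without vehicle replicate 3 (adjusted p = 0.0728) or TNFα replicate 3 (adjusted p = 0.0831).

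In the Atg5 knockout, no transcript passed the test for a TNFα response by edgeR, including those already high with vehicle. Cxcl10 was at 53.5 ± 4.58 CPM with vehicle and 61.8 ± 0.603 CPM with TNFα (mean ± SD, n = 3; log2 fold change ± SE 0.21 ± 0.07, adjusted p = 0.22). B2m stood at 329.5 ± 22.6 and 384 ± 8.07 CPM (0.22 ± 0.05, adjusted p = 0.123). Nfkbia (0.07 ± 0.10, adjusted p = 0.811), Ccl5 (0.21 ± 0.10, adjusted p = 0.401) and H2-K1 (0.14 ± 0.10, adjusted p = 0.535) did not pass. edgeR called 0 genes, with 1771 at an unadjusted p under 0.05, and DESeq2 called 69 (15 higher and 54 lower), B2m among them (adjusted p = 0.00438). In simulated counts of this comparison the test recovered 90 of 100 genes changed 1.5-fold. Those counts were drawn from control vehicle levels with no length trend, so recovery in the data may have been lower. For MHC class I, of 20 members tested, 0 were higher, 0 were lower and 20 were not called (2 higher and 0 lower adjusted over the list alone). The median was 0.10 (camera adjusted p = 5.76e-04, 0.174 with an estimated correlation). Of the chemokines and cytokines, of 14 members tested, 0 were higher, 0 were lower and 14 were not called (2 higher and 0 lower adjusted over the list alone). The median was 0.11 (camera adjusted p = 0.0325, 0.174 with an estimated correlation), a call lost after the length correction (adjusted p = 0.0869). For oxidative phosphorylation, 0 of 28 members tested were called (0 adjusted over the list alone). The median was 0.10 (camera adjusted p = 4.09e-09, 0.306 with an estimated correlation). For mitochondrial transcripts, of 13 members tested, 0 were higher, 0 were lower and 13 were not called (7 higher and 0 lower adjusted over the list alone). The median was 0.27 (camera adjusted p = 3.06e-07, 0.272 with an estimated correlation). In a fit of these 6 libraries alone 28 genes were called.

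In the double knockout, TNFα changed 18 genes by edgeR, 9 higher and 9 lower, with 1195 at an unadjusted p under 0.05 and 72 called by DESeq2. The median longest transcript was 2300 nt for the higher and 10614 nt for the lower genes. With the length correction 15 genes were called, 11 of them among the 18. Rgs16 rose from 58.3 ± 4.41 to 78.6 ± 4.47 CPM (mean ± SD, n = 3; log2 fold change ± SE 0.43 ± 0.07, adjusted p = 0.00973). Syne2, a nuclear envelope linker, fell from 120.2 ± 10.3 to 86.6 ± 8.21 CPM (-0.48 ± 0.07, adjusted p = 0.00299), and Oca2 fell from 23.8 ± 0.753 to 17.8 ± 0.204 CPM (-0.42 ± 0.08, adjusted p = 0.0247). Nfkbia stood at 0.48 ± 0.11, adjusted p = 0.0841, and passed with DESeq2 (adjusted p = 0.0105) and without TNFα replicate 3 (0.62, adjusted p = 0.00749). Cxcl10 (0.17 ± 0.06, adjusted p = 0.421) and B2m (0.15 ± 0.05, adjusted p = 0.247) did not pass. For the interferon-stimulated list, 0 of 40 members tested were called (0 adjusted over the list alone). The median was -0.17 (camera adjusted p = 7.31e-10, 0.272 with an estimated correlation). Of the pigmentation genes, of 19 members tested, 0 were higher, 1 was lower and 18 were not called (0 higher and 5 lower adjusted over the list alone). The median was -0.10 (camera adjusted p = 3.27e-07, 0.104 with an estimated correlation). For chemokines and cytokines, 0 of 14 members tested were called (0 adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.0346, 0.174 with an estimated correlation), a call lost without control vehicle replicate 2 (adjusted p = 0.0523) and after the length correction (adjusted p = 0.0869). In the glycolysis and hypoxia list, 0 of 25 members tested were called (0 adjusted over the list alone). The median was 0.11 (camera adjusted p = 1.14e-07, 0.414 with an estimated correlation). For mitochondrial transcripts, 0 of 13 members tested were called (0 adjusted over the list alone). The median was 0.19 (camera adjusted p = 5.37e-04, 0.45 with an estimated correlation). The count was 9 without vehicle replicate 1, 5 without vehicle replicate 2, 0 without vehicle replicate 3, 2 without TNFα replicate 1, 0 without TNFα replicate 2 and 33 without TNFα replicate 3. Without vehicle replicate 3 the adjusted p was 0.129 for Rgs16, 0.0662 for Syne2 and 0.119 for Oca2, without TNFα replicate 2 it was 0.158, 0.0687 and 0.158, and for Oca2 it was 0.0872 without vehicle replicate 2 or TNFα replicate 1. The TNFα responses of the Rnf31 and double knockouts share no library, and they had 5 higher genes and 1 lower gene in common, against 0.0812 and 0.0240 for independent lists.

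**Figure D3:**
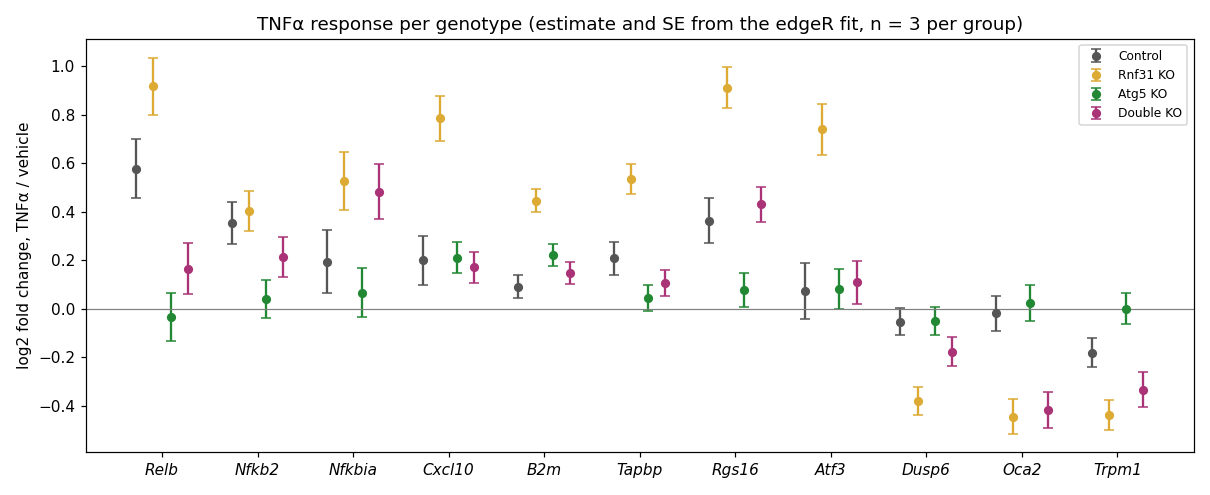
Log2 fold change of TNFα over vehicle (vertical axis) for 11 genes (horizontal axis) in control (grey), Rnf31 knockout (yellow), Atg5 knockout (green) and double knockout cells (purple), as the edgeR estimate with its SE, n = 3 per group. Relb passed in the Rnf31 knockout (0.92, adjusted p = 5.55e-05) and not in control (0.58, adjusted p = 0.0551), Atg5 knockout (-0.04, adjusted p = 0.904) or double knockout cells (0.17, adjusted p = 0.69).

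Whether the TNFα response differed between genotypes was tested as a difference of responses. The median response of the NF-kB list was 0.05 in control, 0.12 in the Rnf31 knockout, -0.02 in the Atg5 knockout and 0.09 in the double knockout, where the mean was -0.08. Of these 4 responses the one in the Rnf31 knockout passed (camera adjusted p = 1.88e-04, 0.0879 with an estimated correlation), and camera adjusted p-values of the others were 0.4 in control, 0.905 in the Atg5 knockout and 0.0513 in the double knockout. After the length correction the list passed in the double knockout (higher, adjusted p = 0.0284). Differences of this list from control did not pass in the Rnf31 (0.09, camera adjusted p = 0.113), Atg5 (-0.10, 0.512) or double knockout (0.07, with a mean of -0.16, 0.915). Without control vehicle replicate 2 the difference of the Rnf31 knockout passed (higher, adjusted p = 0.008). Against control, the Rnf31 knockout response differed in 1 gene by edgeR, Tmod1, an actin-capping protein gene (log2 difference ± SE 0.52 ± 0.08, adjusted p = 0.00689), with 1643 genes at an unadjusted p under 0.05. DESeq2 called 53 genes, 28 higher and 25 lower, and the length correction gave 14, 9 higher and 5 lower. The Tmod1 call was lost without control TNFα replicate 3 (adjusted p = 0.0594). The count of 1 became 113 without control vehicle replicate 1, 6 without control vehicle replicate 2, 2 without control vehicle replicate 3, 4 without control TNFα replicate 2 and 0 without control TNFα replicate 3. For mitochondrial transcripts, of 13 members tested, 0 were higher, 0 were lower and 13 were not called (1 higher and 0 lower adjusted over the list alone). The median was 0.30 (camera adjusted p = 8.50e-05, 0.377 with an estimated correlation).

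The Atg5 knockout response differed from that of control in 1536 genes by edgeR, 668 higher and 868 lower, and DESeq2 called 2309. Relb responded less (-0.61 ± 0.16, adjusted p = 0.0196), as did Ubr4 (-0.73 ± 0.09, adjusted p = 2.42e-04), the proliferation marker Mki67 (-0.55 ± 0.08, adjusted p = 0.00148) and the ubiquitin ligase Trim62 (-0.92 ± 0.15, adjusted p = 0.00232). Nme3, a nucleoside diphosphate kinase gene, responded more (0.74 ± 0.15, adjusted p = 0.00799). For oxidative phosphorylation, of 28 members tested, 18 were higher, 0 were lower and 10 were not called (22 higher and 0 lower adjusted over the list alone), with a median difference of 0.29 (camera adjusted p = 1.67e-10, 0.272 with an estimated correlation). After the length correction that median was 0.07. For mitochondrial transcripts, 0 of 13 members tested were called (0 adjusted over the list alone). The median was 0.36 (camera adjusted p = 0.00135, 0.491 with an estimated correlation), a call lost after the length correction (adjusted p = 0.175). The median longest transcript was 1718 nt for the higher genes and 6628 nt for the lower genes, and with the length correction 231 genes were called, 140 higher and 91 lower, 169 of them among the 1536, while the Nme3 call was lost as its fold shrank (0.45 ± 0.12, adjusted p = 0.0591). The count was 3155 without control vehicle replicate 1, 325 without control vehicle replicate 2, 483 without control TNFα replicate 1, 717 without control TNFα replicate 3, 854 without Atg5 knockout vehicle replicate 2, 586 without Atg5 knockout vehicle replicate 3 and 293 without Atg5 knockout TNFα replicate 2.

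**Figure D4:**
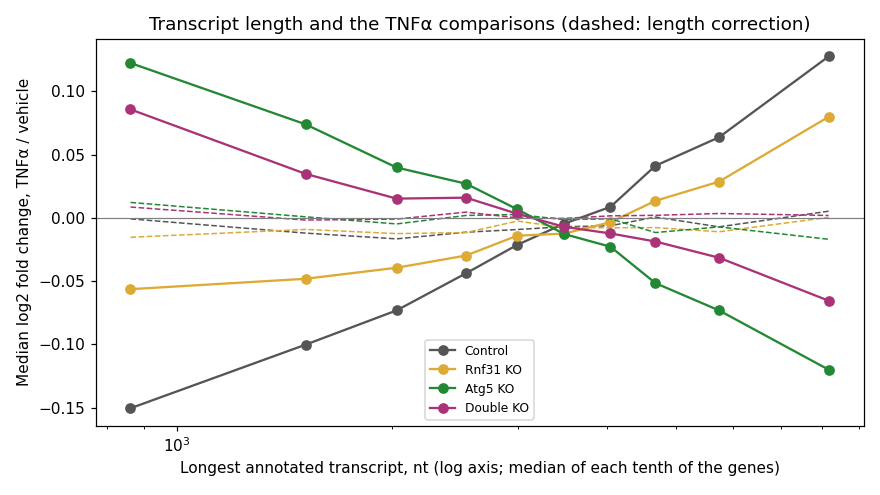
Median log2 fold change of TNFα over vehicle (vertical axis) in 10 equal bins of the genes by longest annotated transcript in nt (horizontal axis, log scale) for the 4 genotypes, with dashed lines after the length correction. In control cells the median ran from -0.15 in the bin of shortest transcripts (862 nt) to 0.13 in the longest (8171 nt), and in the Atg5 knockout from 0.12 to -0.12.

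The double knockout response differed from that of control in 156 genes by edgeR, 52 higher and 104 lower, and DESeq2 called 805, 460 higher and 345 lower. Syne2 (-0.77 ± 0.10, adjusted p = 2.12e-04) and Ubr4 (-0.71 ± 0.09, adjusted p = 2.12e-04) were among the lower genes. For oxidative phosphorylation, of 28 members tested, 1 was higher, 0 were lower and 27 were not called (22 higher and 0 lower adjusted over the list alone), with a median difference of 0.23 (camera adjusted p = 3.42e-11, 0.272 with an estimated correlation), beside mitochondrial transcripts with a median of 0.25 (camera adjusted p = 0.0172, 0.586 with an estimated correlation). The mitochondrial call was lost without control vehicle replicate 2 (adjusted p = 0.134) and after the length correction (adjusted p = 0.712). With the length correction 2 genes were called, both higher and neither among the 156, and Syne2 (-0.40 ± 0.08, adjusted p = 0.0644) and Ubr4 (-0.39 ± 0.08, adjusted p = 0.0753) lost their calls as their folds shrank. The count was 1773 without control vehicle replicate 1, 30 without control vehicle replicate 2, and 21, 39 and 33 without control TNFα replicates 1, 2 and 3. It was 503, 19 and 26 without double knockout vehicle replicates 1, 2 and 3, and 13, 31 and 877 without double knockout TNFα replicates 1, 2 and 3.

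Between the double and the Rnf31 knockout, 53 genes had a lower response and none a higher one by edgeR. Cxcl10 was among them (-0.61 ± 0.11, adjusted p = 0.0119), with Syne2 (-0.73 ± 0.10, adjusted p = 4.84e-04) and the transcription factor Zbtb20 (-0.84 ± 0.12, adjusted p = 4.84e-04). DESeq2 called 109 genes, 29 higher and 80 lower, and the length correction gave 6, 3 higher and 3 lower, 3 of them among the 53, and Syne2 (-0.37 ± 0.08, adjusted p = 0.064) and Zbtb20 (-0.43 ± 0.11, adjusted p = 0.178) lost their calls as their folds shrank. The count was 19 without Rnf31 knockout vehicle replicate 1 or 2, 16 without Rnf31 knockout TNFα replicate 3, 22 and 15 without double knockout vehicle replicates 2 and 3, and 11 and 30 without double knockout TNFα replicates 1 and 2. Between the double and the Atg5 knockout, edgeR called 1 gene, Gm26571, which was chosen after its values were seen (-2.79 ± 0.48, adjusted p = 0.0465), with 747 genes at an unadjusted p under 0.05 and 2 called by DESeq2, 1 higher and 1 lower. That call was lost without Atg5 knockout vehicle replicates 2 or 3, Atg5 knockout TNFα replicates 1 or 2, double knockout vehicle replicates 2 or 3 or double knockout TNFα replicates 1 or 2, each of which gave 0 genes. It was also lost with the stricter filter (adjusted p = 0.0503) and in the fit of only the groups compared (adjusted p = 0.0518). For interferon-stimulated genes in that difference, of 40 members tested, 0 were higher, 0 were lower and 40 were not called (0 higher and 1 lower adjusted over the list alone), with a median difference of -0.18 (camera adjusted p = 3.42e-11, 0.243 with an estimated correlation). For pigmentation genes, of 19 members tested, 0 were higher, 0 were lower and 19 were not called (0 higher and 2 lower adjusted over the list alone). The median was -0.11 (camera adjusted p = 3.00e-05, 0.174 with an estimated correlation). The response difference of the double knockout was set against the sum of those of the single knockouts, and edgeR called 0 genes, with 1450 at an unadjusted p under 0.05 and 12 called by DESeq2. Without control vehicle replicate 1 edgeR called 4. Over all comparisons, 84 of 312 list tests passed with the preset correlation and 4 with an estimated one: NF-kB targets and chemokines and cytokines in the Atg5 knockout against control, and interferon-stimulated genes and MHC class I in the double knockout against control.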

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

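The comparisons of responses and the regroupings of libraries below were planned, while the length correction, the test of the NF-kB list as an explanation and the list test without 1 library were chosen after the data were seen. Each result here is a TNFα response that differed between genotypes, or a signal in a part of the table that the comparisons do not use.

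Among genes whose TNFα response differed between the Atg5 knockout and control were Relb (-0.61), Ubr4 (-0.73), Mki67 (-0.55), Trim62 (-0.92) and Nme3 (0.74), as log2 differences. Oxidative phosphorylation genes had a median difference of 0.29 and mitochondrial transcripts 0.36, calls lost with an estimated correlation (adjusted p = 0.272 and 0.491). With the length offset the medians were 0.07 and 0.14, and the mitochondrial call was lost (adjusted p = 0.175).

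That response differed in 1536 genes. Of 77 ways to assign the treatment labels within these genotypes 1, the real one, gave as many, with 0 in the highest other. This makes chance unlikely but does not exclude it, since the labels were redrawn in all genotypes at once. A transcript-length effect between libraries may account for most of the 1536 calls. With a length offset per library 231 genes were called, 169 of them among the 1536. Relb (-0.61), Ubr4 (-0.42), Mki67 (-0.29) and Trim62 (-0.89) kept their calls there and Nme3 (0.45, adjusted p = 0.0591) did not. Simulated counts with a set length trend in control vehicle libraries alone gave 11 calls. In the data the median difference ran from 0.27 in the bin of shortest transcripts to -0.25 in the longest. The Atg5 knockout response trended as well (0.12 to -0.12), so the 11 calls do not bound what length can account for. Whether 1 deviating control library could account for the 1536 calls was not decided, because the count was 325 without control vehicle replicate 2 and 293 without Atg5 knockout TNFα replicate 2. A different action of TNFα on its target genes stays open, as the NF-kB list did not pass (adjusted p = 0.512) but had a median of -0.10.

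The double knockout response differed from that of control in 156 genes, with Syne2 at -0.77 and Ubr4 at -0.71. Oxidative phosphorylation genes had a median of 0.23 and mitochondrial transcripts 0.25 in that difference, calls lost with an estimated correlation (adjusted p = 0.272 and 0.586). Of 74 distinct assignments 1, the real one, gave as many genes and the highest other gave 1. Chance is unlikely for the 156 but not excluded, since these labels were also redrawn in all genotypes at once. With the length offset 2 genes were called, neither among the 156, and Syne2 stood at -0.40 and Ubr4 at -0.39. The Rnf31 knockout response differed from that of control in 1 gene, Tmod1 (0.52), and mitochondrial transcripts had a median difference of 0.30 (adjusted p = 0.377 with an estimated correlation). For that count of 1, 6 of 82 assignments gave at least as many, the highest other 24, so chance cannot be excluded. Between the double and the Rnf31 knockout the response differed in 53 genes, with Cxcl10 at -0.61, Syne2 at -0.73 and Zbtb20 at -0.84. Here 2 of 81 assignments, the real one included, gave at least as many, and the other one gave 55, so chance stays open. With the length offset 6 were called, 3 among the 53, and Cxcl10 stood at -0.65, Syne2 at -0.37 and Zbtb20 at -0.43. Between the double and the Atg5 knockout the response differed in 1 gene, Gm26571 (-2.79), with 4 of 82 assignments giving at least 1 gene and the highest other 2, and a single call at an adjusted p of 0.0465, lost without any 1 of 8 libraries, leaves chance open. In the same difference, interferon-stimulated genes had a median of -0.18 and pigmentation genes -0.11 (adjusted p = 0.243 and 0.174 with an estimated correlation). For the departure from additive responses, with 0 genes by edgeR, 1450 at an unadjusted p under 0.05 and 12 by DESeq2, any assignment gives at least as many (100 of 100, the highest other 3), so the regrouping says nothing about chance.

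The row with no gene name held 0.617% of the counts in Atg5 knockout TNFα replicate 1 (95% Wilson interval 0.614% to 0.620%) and 0.832% in double knockout TNFα replicate 3 (0.828% to 0.836%). The highest share in a control vehicle library was 0.163% (0.162% to 0.165%).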

How the results depend on the processing

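The length correction and the list tests without control vehicle replicate 2 were chosen after the data were seen, and every other alternative was planned. RLE size factors moved none of the 13 counts by more than 1.5 times. Of 166 results for single named genes, 146 were the same under every alternative but the size threshold, 19 lost or gained a call in at least 1 of them and 0 reversed. Below, responses means TNFα responses and differences means those of the responses against control unless another line is named, and the cause was not tested where none is given. DESeq2 called 682 (control), 244 (Rnf31 knockout), 69 (Atg5 knockout) and 72 (double knockout) genes for the responses. It called 53, 2309 and 805 for the differences of the Rnf31, Atg5 and double knockouts, 109 and 2 for the double against the Rnf31 and the Atg5 knockout, and 12 for non-additivity. Tested against a 2-fold change, a stricter question, 0 genes passed for the responses of control, Rnf31 and double knockout and for the 5 differences that had calls, and 6, 808 and 413 for the Rnf31, Atg5 and double knockouts against control. Under it 3 target calls were also lost, with Rnf31 at -0.28 and -0.57 in the Rnf31 and double knockouts and Atg5 at -1.11 in the double knockout. Fits of only the groups compared, with fewer libraries behind the spread, gave 0, 331, 28 and 8 for the responses in the same order, 504 and 5 for the differences of the Atg5 and double knockouts, 2 for the double against the Atg5 knockout, neither of them Gm26571, and -0.30 for Rnf31 in its knockout (adjusted p = 0.0611). The length correction gave 0 for the control response, 14, 231 and 2 for the differences of the Rnf31, Atg5 and double knockouts, and 6 for the double against the Rnf31 knockout. Without a filter 94 genes and with a stricter filter 117 were called for the control response, against 13, and 2 and 0 for the double against the Atg5 knockout, against 1. Robust estimation gave 68 for the control response and 3 for the difference of the Rnf31 knockout. With a replicate block the counts were 182 for the control response, 34 for the double knockout response, 11 and 533 for the differences of the Rnf31 and double knockouts and 2 for the double against the Atg5 knockout, Relb gained a call in the control response, and MHC class I genes lost their call in the Rnf31 knockout response (adjusted p = 0.0565) while NF-kB targets gained one in the double knockout response (adjusted p = 0.0402). Same-numbered libraries had correlated deviations of -0.098 to 0.0788 between groups, and 13 of 24 libraries matched best with their own number. Rank correlations of these deviations with transcript length, for replicates 1, 2 and 3, were -0.29, -0.02 and 0.27 in double knockout vehicle libraries. With TNFα in that line they were -0.24, -0.03 and 0.23. In the Atg5 knockout they were -0.19, 0.08 and 0.09 with vehicle and 0.04, -0.19 and 0.15 with TNFα. Whether the numbers pair the libraries was thus not settled. Of 84 list calls, 4 held with an estimated correlation. Leaving out each library in turn gave 0 to 2200 genes for the control response, 72 to 123 for the Rnf31 knockout, 0 for the Atg5 knockout and 0 to 33 for the double knockout. The ranges were 4676 to 6454, 7890 to 8200 and 6346 to 7116 for the Rnf31, Atg5 and double knockouts against control, and 0 to 113, 293 to 3155 and 13 to 1773 for their differences. They were 11 to 61 and 0 to 1 for the double against the Rnf31 and the Atg5 knockout and 0 to 4 for non-additivity. Rnf31 ranged from -0.37 to -0.21 in its knockout, where the call was lost in 4 cases, and from -0.65 to -0.49 in the double knockout, and Atg5 from -1.39 to -1.21 and from -1.17 to -1.01 in the Atg5 and double knockouts, with every call held. Cxcl1 had 4 counts over the control vehicle libraries, so depth limits what is known of its level there.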

Other observations

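The comparison of the double with the Atg5 knockout, and the tests of leukocyte RNA, of another line difference and of Rnf31 loss in any line, were chosen after the data were seen, as was the length correction, while the regroupings of libraries were planned. With vehicle, double knockout cells held fewer NF-kB target transcripts than Atg5 knockout cells, and more interferon-stimulated ones. In the NF-kB list of 21 tested members 1 was higher and 17 lower, median -0.99 (camera adjusted p = 5.26e-11, 3.32e-04 with an estimated correlation), with Nfkbiz (-1.73 ± 0.09), Nfkbia (-1.50 ± 0.11), Tnfaip3 (-1.10 ± 0.17) and Relb (-0.88 ± 0.10) as log2 fold change ± SE. For chemokines and cytokines of 14 tested members 1 was higher and 6 lower, median -1.26 (camera adjusted p = 0.00112, 0.0118 with an estimated correlation), with Cxcl1 (-6.04 ± 0.11) and Csf1 (-2.02 ± 0.08) lower and Cxcl10 (0.31 ± 0.06) higher. In the dedifferentiation and matrix list of 22 tested members 1 was higher and 16 lower, median -0.78 (camera adjusted p = 7.53e-09, 0.0131 with an estimated correlation), among them Fn1 (-1.69 ± 0.08) and Axl (-1.55 ± 0.07). Of interferon-stimulated genes, of 40 tested members 29 were higher and 2 lower, median 0.65 (camera adjusted p = 8.21e-15, 0.029 with an estimated correlation), with Rtp4 (1.13 ± 0.08) and Oas1a (0.63 ± 0.08), while Irf1, which NF-kB also induces, was lower (-0.78 ± 0.07). Every gene given here had an adjusted p of at most 4.20e-04. In all 5150 genes differed by edgeR, 2466 higher and 2684 lower in the double knockout (n = 3 per group).

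Other lists also passed between the double and the Atg5 knockout, the first 5 given with medians against control in the Atg5 and the double knockout. For proliferation of 32 tested members 22 were higher and 0 lower, median 0.18 (camera adjusted p = 7.53e-09, 0.00882 with an estimated correlation), with Rrm2 (0.63 ± 0.04), and the medians against control were -0.35 and -0.17. In the pigmentation list of 19 tested members 13 were higher and 1 lower, median 0.23 (camera adjusted p = 3.14e-06, 0.0233 with an estimated correlation), with Mlana (0.35 ± 0.05), and the medians against control were -0.55 and -0.30. For chaperones of the endoplasmic reticulum of 16 tested members 11 were higher and 0 lower, median 0.28 (camera adjusted p = 1.44e-08, 0.00882 with an estimated correlation), with Hspa5 (0.44 ± 0.05) and Manf (0.59 ± 0.06), and the medians against control were -0.37 and 0.01. In the glycolysis and hypoxia list of 25 tested members 0 were higher and 20 lower, median -0.39 (camera adjusted p = 1.17e-10, 0.103 with an estimated correlation), with Vegfa (-0.52 ± 0.09), and the medians against control were 1.75 and 1.47. For p53 targets of 19 tested members 0 were higher and 13 lower, median -0.37 (camera adjusted p = 5.91e-05, 0.0181 with an estimated correlation), and 0.02 and -0.15 against control, where neither passed. For cholesterol synthesis of 22 tested members 15 were higher and 0 lower, median 0.26 (camera adjusted p = 1.25e-06, 0.0289 with an estimated correlation). In the integrated stress response list of 26 tested members 3 were higher and 16 lower, median -0.30 (camera adjusted p = 1.96e-05, 0.0434 with an estimated correlation). For autophagy genes of 36 tested members 3 were higher and 15 lower, median -0.14 (camera adjusted p = 0.00576, 0.0172 with an estimated correlation). In the heat shock list of 12 tested members 8 were higher and 1 lower, median 0.22 (camera adjusted p = 0.00295, 0.0402 with an estimated correlation). For immediate early genes, which also respond to handling, of 15 tested members 2 were higher and 8 lower, median -0.39 (camera adjusted p = 0.00196, 0.0375 with an estimated correlation). Immune ligands and the TNF receptor complex passed with the preset correlation and not with an estimated one (adjusted p = 0.0624 and 0.0988).

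NF-kB targets were lower in double than in Atg5 knockout cells, by a median of -0.99. With the length offset the median was -0.99, so a trend with transcript length does not account for it. That loss of Rnf31 lowers the list in any line is argued against, as its median in the Rnf31 knockout against control was 0.10. A candidate explanation is that Rnf31 contributes to NF-kB activity that arises when Atg5 is lost, which would need a line restored for Rnf31, and the lines may also differ in other ways or in handling.

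Interferon-stimulated genes were higher in the Atg5 knockout than in control, by a median of 3.14 (camera adjusted p = 9.76e-18, adjusted p = 0.168 with an estimated correlation). With the length offset the median was 3.09, and RNA from leukocytes is argued against, since the largest rise of an abundant leukocyte marker was 3.83 CPM (Cd68), below the 50 CPM set as needed. The double knockout, labelled with the same deletion, shared the rise (3.72). A line difference other than Atg5 cannot be told apart from the deletion, because the labels do not say whether the double knockout was derived from the Atg5 knockout. Loss of Atg5 thus stays a hypothesis that may hold, beside a difference of the lines.

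Each comparison of 2 groups allows 10 splits of its 6 libraries, too few for a share under 0.05. For the TNFα responses, 1 of 10 splits gave as many genes in control cells (13 genes, highest other 1), the Rnf31 knockout (158, highest other 0) and the double knockout (18, highest other 0), while for the count of 0 in the Atg5 knockout any split gives as many, 10 of 10, which says nothing (0 by edgeR, 1771 at an unadjusted p under 0.05, 69 by DESeq2; highest other 0). Against control with vehicle, 1 of 10 splits gave as many in the Rnf31 (6165), Atg5 (8393) and double knockout (7093), with 0 in the highest other.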
